A study of Homo sapiens with 2 samples.

How the data were processed

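Per the labels' protocols, total RNA was extracted with Trizol and libraries were made by a standard Illumina method. Whether poly(A) RNA was selected, and whether libraries were stranded, is not given in the sources used here. HISAT2 2.0.5 and the genome build hg18 are named in the submitters' processing notes. The read counter, the gene annotation and the FPKM formula are not given in the sources used here. Each of the 2 deposited tables holds FPKM, a read count scaled for gene length and sequencing depth, for 58735 Ensembl genes, per the file headers, with no counts. Groups were taken from the sample titles: 1 scrambled and 1 shSIK2 library, both from BT549 cells given Wnt3a for 2 h.

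All 58735 gene identifiers matched GENCODE release 29 on GRCh38, which gave symbols, gene types, exon lengths, GC content and all coordinates printed here. That annotation differs from the build named in the processing notes, and which build was aligned to is not settled. Multiplying each deposited FPKM value by the exon length of its gene gave whole multiples of a step of 58.3, the same in both tables, for 100% of the 21622 and 22790 values above 0 (tolerance 0.001). The multiples were taken as reads assigned to each gene, with totals of 18019225 (scrambled) and 16347399 (shSIK2). The step corresponds to the same divisor in both libraries, the geometric mean of the 2 totals. The deposited FPKM values are therefore scaled for gene length and not to the read total of each library. Values left unscaled for depth and values after median of ratios scaling cannot be told apart here, since that scaling shifts the log2 ratios by 0. Among the 19394 genes with reads in both libraries the median log2 ratio was 0, as median of ratios scaling would give, and 925 had equal reads. Scaling to equal totals adds 0.14 to each log2 ratio of shSIK2 over scrambled, a factor of 1.10, and moves the median of all measured genes from -0.11 to 0.03.

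Before the data were examined, the groups, the alternatives, 34 gene lists, the rules of size and the rule for named genes were fixed. With 1 library per group there was no test, no p-value and no leave-out check. A gene was measured with at least 1 FPKM in the higher library. Log2 ratios are of shSIK2 over scrambled, of FPKM plus a pseudocount of 0.1 as deposited, which understates the ratio of low genes. Genes were counted as higher or lower at 2-fold on that scale. Folds in the text are ratios of recovered reads, with an exact (Clopper-Pearson, conditional on the sum) 95% interval. Where a library had 0 reads the fold is a lower bound against 3 reads, with the reads of the other library taken as they are. The exact interval starts lower, at 95.7-fold for HSPA6, 65.4-fold for SFN and 9.27-fold for DEFB115. Reads without molecular identifiers are not independent molecules, so intervals and bounds cover counting error only. Named genes were SIK2, SIK1, SIK3, LRP6, CTNNB1 and AXIN2; the 10 highest and 10 lowest log2 ratios among protein-coding genes with at least 5 FPKM in the higher library; and up to 4 members of each list with the largest absolute log2 ratio. 1 list member that the last part of this rule picks is withheld from the text. Others that it picks are not named for some lists, such as the G2/M genes and ribosomal proteins. All stay in the counts and medians. List members named beyond these were chosen after their values were seen.

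A list's median is given relative to the median of all measured genes, with its percentile among 10000 random lists of equal size matched on mean expression in 20 bins. The percentiles describe these libraries and are not p-values. Order-statistic intervals of a median show the spread between members only. GC and length trends were removed by subtracting medians in 20 bins of GC content and 20 of exon length, repeated once. Segments along chromosomes came from repeated splits of these residuals at the largest rank-sum statistic, with at least 20 genes on each side. A split was kept where it passed the value that 95% of 100 shuffles of gene order stayed under. Software was Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

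Read recovery, the 2-fold rule, counting intervals, random lists, trend removal and chromosome splits were tested on simulated data, with counting error only; the removal of segment medians was not. Reads were recovered exactly for 100% of values. Of 12429 genes measured in the simulated comparison of shSIK2 with scrambled, the 2-fold rule called 98.0% of genes changed by 4-fold, 3.03% of those changed by 1.5-fold and 2.47% of unchanged genes. Counting intervals held the true ratio for 95.4% of genes, and 5.90% of unchanged lists fell outside the 2.5th to 97.5th percentiles. After removal of an added trend the rank correlation of ratios with GC content was 0.0129, and a list shifted by 1 kept a median of 0.98. In 100 simulated chromosomes of 560 genes, 0% split without a shift, and the edge of a shifted stretch was found within 30 genes in 100%. The simulated genes were drawn independently of their neighbours, with a shift of fixed size near the middle of the chromosome. These shares therefore do not show how splits behave with smaller steps, shorter stretches or correlated neighbours.

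The alternatives fixed beforehand were total count, median of ratios and upper quartile scaling, pseudocounts of 0.01 and 1, minimum levels of 0.1 and 5 FPKM or none, folds of 1.5 and 4, protein-coding genes only, a Bonferroni-corrected counting interval, means of lists, unmatched random lists and library totals without mitochondrial genes. TMM scaling of the recovered reads, a minimum of 50 reads, removal of the GC and length trend and removal of segment medians were added after the data had been seen. The recovered depth leaves 463 of the higher and 297 of the lower genes with under 50 reads in their higher library, and their ratios are the least precise.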

Results

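The data were RNA sequencing profiles of BT549, a triple-negative breast cancer cell line with mesenchymal features. Both cultures had been given the ligand Wnt3a for 2 h. The scrambled group carried a control hairpin and the shSIK2 group a short hairpin RNA against SIK2, a salt-inducible kinase. Each group held 1 library. The recovered depth was 18019225 reads assigned to genes in the scrambled library and 16347399 in the shSIK2 library. With 1 library per group no difference has a replicate check, and no p-value is given. Intervals beside a fold cover counting error only. The comparison asks how a lower SIK2 level goes with the transcripts of Wnt3a-treated cells, in a series whose title concerns LRP6, beta-catenin signalling and stem-like breast cancer cells.

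SIK2 (ENSG00000170145, GRCh38 chromosome 11, 111602391 to 111730853) was lower in the shSIK2 library, at 3.56 FPKM against 7.80 in the scrambled library. Its exonic reads were 599 and 1312, a 2.19-fold difference (95% counting interval 1.99 to 2.42). The log2 ratio was -1.11 as deposited and -0.97 when both libraries were scaled to their total reads. Of the 12866 genes measured, 817 (6.35%) were at least as low as SIK2. SIK1, a related kinase on chromosome 21, was 3.46-fold lower (3.02 to 3.96), and SIK3 was 1.78-fold lower (1.60 to 1.97). The list of SIK kinases and the upstream LKB1 complex had 7 measured members, 2 of them (SIK1 and SIK2) at least 2-fold lower and 0 higher. CAB39, a scaffold of that complex, was 1.58-fold lower (1.46 to 1.72). At equal totals SIK1 alone was 2-fold lower. The list median was -0.55 relative to all measured genes on the log2 scale (percentile 2.02 among random lists). It stood at percentile 10.7 after a trend with GC content and length was removed. SIK2, the target of the hairpin, is among the members, and no list value without it was computed.

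At least 2-fold higher in the shSIK2 library were 1414 genes, 10.99% of those measured. At least 2-fold lower were 1065 genes, or 8.28%. Scaling to total reads gave 1723 and 777, so the higher genes made up 57.0% of the differing genes as deposited and 68.9% at equal totals. The ratio exceeded counting error after Bonferroni correction for 935 of the higher and 748 of the lower genes. Across genes, which are not independent replicates, the log2 FPKM of both libraries correlated with a Pearson r of 0.87. The log2 ratio followed GC content across protein-coding genes (Spearman rho 0.34): the median was -0.31 in the tenth of genes with the lowest GC content and 0.44 in the tenth with the highest.

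**Figure D1:**
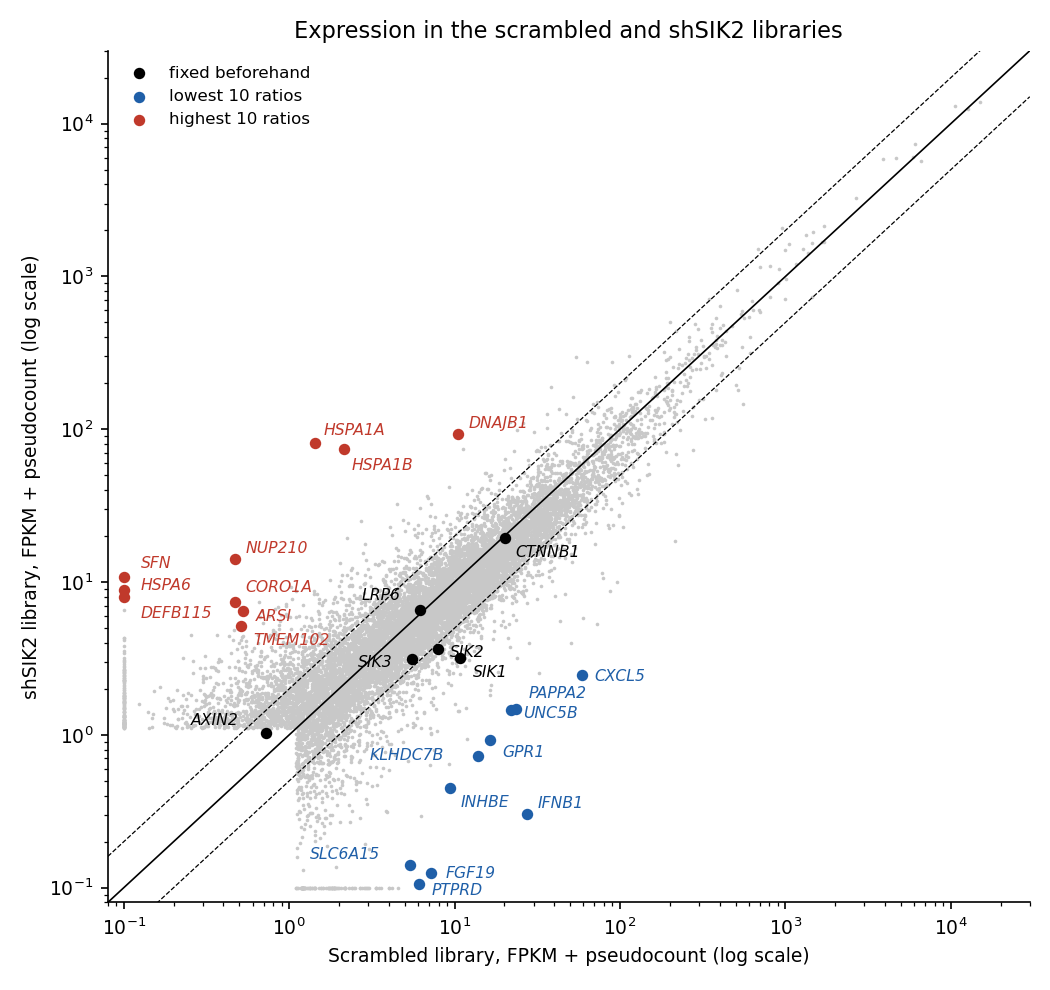
FPKM plus a pseudocount of 0.1 in the scrambled library (x axis) and the shSIK2 library (y axis), both on log scales, for the 12866 measured genes (grey points) and the named genes (coloured points). The solid line marks equal values and the dashed lines 2-fold differences. HSPA1A and HSPA1B lie far above the upper dashed line, and IFNB1 and PTPRD far below the lower one.

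The 10 protein-coding genes with the lowest ratios included secreted signals and surface proteins. IFNB1, which encodes interferon beta (chromosome 9, 21077105 to 21077963), had 405 reads in the scrambled library and 3 in the shSIK2 library, a 135-fold difference (45.9 to 657). FGF19, an endocrine growth factor, had 299 reads against 1 (299-fold, 53.3 to 11849). PTPRD, a receptor tyrosine phosphatase (chromosome 9, 8314246 to 10612723), had 1145 reads against 1 (1145-fold, 205 to 45264). IFNB1 and PTPRD lie in a chromosome 9 segment whose genes were low as a group, with a median of -0.49 after the GC and length trend was removed. SLC6A15, an amino acid transporter, was 132-fold lower (60.3 to 360). CXCL5, a neutrophil chemokine, stood at 58.6 FPKM in the scrambled library and 2.36 in the shSIK2 library, 24.8-fold lower (20.3 to 30.5). INHBE, KLHDC7B, GPR1, PAPPA2 and UNC5B were 26.8-fold, 22.1-fold, 19.8-fold, 16.8-fold and 16.01-fold lower, in that order.

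Heat shock genes made up 4 of the 10 protein-coding genes with the highest ratios. HSPA6, an inducible HSP70, had 0 reads in the scrambled library and 355 in the shSIK2 library, at least 118-fold higher against the 3 reads that a count of 0 allows. HSPA1A and HSPA1B, the neighbouring inducible HSP70 genes of chromosome 6, stood at 81.1 FPKM against 1.34 and 74.4 FPKM against 2.03. The folds were 60.6 (46.7 to 80.2) and 36.6 (29.6 to 45.7). Both genes are nearly identical, so how their reads divide between them is uncertain. DNAJB1, an HSP70 co-chaperone, was 8.93-fold higher (8.24 to 9.69). SFN, the 14-3-3 sigma protein, had 0 and 243 reads, at least 81.0-fold higher. NUP210, a nuclear pore glycoprotein, was 37.8-fold higher (28.7 to 50.8), and CORO1A, an actin-binding coronin, 19.6-fold higher (13.7 to 29.1). ARSI and TMEM102 were 14.9-fold (9.84 to 23.5) and 12.3-fold (7.29 to 22.5) higher. DEFB115, with an exonic length of 267 bases, had 0 and 36 reads, at least 12-fold higher.

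Genes of the type I interferon response were low as a group in the shSIK2 library. Of 22 measured members, 13 were at least 2-fold lower, 0 were at least 2-fold higher and 9 lay between; at equal totals 1 member was 2-fold higher. RSAD2, the antiviral protein viperin, was 16.8-fold lower (12.4 to 23.2), OASL 13.9-fold (12.4 to 15.7), IFIT1 13.0-fold (11.6 to 14.7) and IFIT2 9.59-fold (8.87 to 10.4). The list median was -1.58 relative to all measured genes (95% order-statistic interval -2.80 to -0.30, spread between members only) and below all 10000 random lists. The NF-kB and inflammatory cytokine list had 17 measured members, 7 at least 2-fold lower and 1 higher. Its median was -0.69 (-0.95 to -0.10; percentile 0.02). Beside CXCL5, its largest ratios were those of the chemokines CCL5, 11.7-fold lower (10.7 to 12.9), and CXCL8, 2.66-fold lower (2.42 to 2.94), and of IL6, 9.98-fold lower (8.87 to 11.3). At equal totals 4 members of this list were at least 2-fold lower and 2 higher.

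Cytosolic heat shock genes were high as a group, with 8 of 14 members at least 2-fold higher and 0 lower. The median was 1.40 relative to all measured genes (0.40 to 5.23) and above all 10000 random lists. HSPA6 was the highest member with its ratio set at its bound as well, so the median does not depend on it. Genes of the unfolded protein and integrated stress response did not follow them, with a median of -0.43 (-0.87 to 0.03, percentile 0.21). Of 28 members, 8 were at least 2-fold lower and 3 higher, or 6 and 4 at equal totals. Among these, the serine synthesis enzymes PHGDH and PSAT1 were 5.4-fold (4.84 to 6.02) and 3.07-fold (2.97 to 3.18) lower. ATF5, a transcription factor of the integrated stress response, was 3.09-fold lower (2.75 to 3.49). SDF2L1, an endoplasmic reticulum chaperone component, was 5.05-fold higher (4.13 to 6.23).

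**Figure D2:**
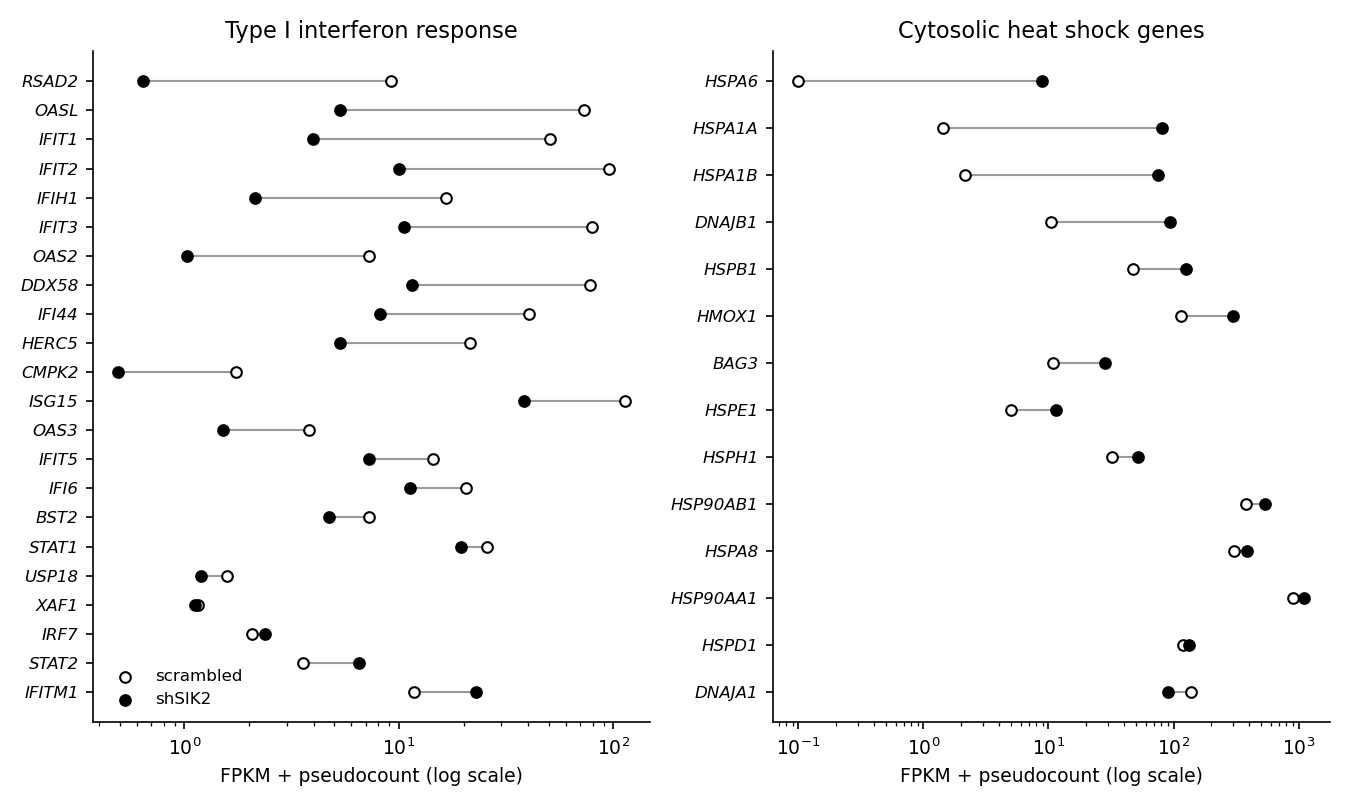
FPKM plus a pseudocount of 0.1 (x axes, log scale) of the 22 measured interferon-response genes (left) and the 14 heat shock genes (right), with open circles for the scrambled library and filled circles for the shSIK2 library (1 library each). At the left, 13 genes were at least 2-fold lower in the shSIK2 library, and at the right 8 were at least 2-fold higher.

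The Wnt pathway lists showed no common direction. Both libraries had Wnt3a, so the response to Wnt3a itself cannot be read from them. LRP6, the Wnt co-receptor, stood at 6.07 FPKM in the scrambled library and 6.43 in the shSIK2 library, a 1.06-fold difference (0.97 to 1.15). CTNNB1, which encodes beta-catenin, stood at 19.99 and 19.4 FPKM, 1.03-fold (0.99 to 1.08). AXIN2, a feedback target of beta-catenin, was below the minimum of 1 FPKM in both libraries, with 56 and 83 reads, 1.48-fold higher in the shSIK2 library (1.04 to 2.12). Of the 18 direct feedback targets 6 were measured, with a median of -0.12 (-0.71 to 2.71; percentile 24.0). Taken without the subtraction of the median of all genes, their median was -0.22 and their mean 0.20. TCF7, a transcription factor of the pathway, was 10.05-fold higher (6.47 to 16.4), from 22 reads to 221, and 0 members were at least 2-fold lower. ZNRF3, DKK1 and BMP4 were 1.86-fold, 1.65-fold and 1.60-fold lower. Of the feedback targets below the minimum, some beside AXIN2 also had more reads in the shSIK2 library, though few. These were NOTUM (18 and 38 reads, scrambled first), NKD2 (13 and 24), NKD1 (1 and 3) and CYP26A1 (0 and 5). The remaining ones had no reads in either library. Of the 20 measured Wnt targets linked to growth and invasion, 2 were at least 2-fold higher and 1 lower. EPHB2, a receptor kinase, was 4.63-fold higher (3.93 to 5.48), S100A4 2.55-fold higher (2.22 to 2.94) and the tight junction gene CLDN1 3.61-fold lower (3.42 to 3.81). That list's median was 0.34 (-0.38 to 0.60, percentile 99.1 among matched and 95.1 among unmatched random lists). It stood at percentile 99.66 after the GC and length trend was removed, and at 99.45 with segment medians removed as well.

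Among 37 measured Wnt receptors, transducers and destruction complex genes, 2 were at least 2-fold higher, 4 at equal totals, and 1 lower (median 0.06, percentile 82.6). KREMEN2, a receptor for DKK inhibitors, was 11.4-fold higher (6.82 to 20.3), TLE3, a corepressor, 3.18-fold higher (2.496 to 4.09) and the receptor FZD4 6.09-fold lower (5.04 to 7.40). Of 8 measured ligands, R-spondins and secreted inhibitors, SFRP1 was 5.4-fold higher (4.93 to 5.93) and WNT10B 2.29-fold lower (1.58 to 3.37; its log2 ratio with the pseudocount was -0.98 at equal totals), with a median of -0.33 (percentile 9.86). Median and mean without that subtraction also differed in sign for both lists, at -0.04 and 0.03 for the receptors and -0.43 and 0.03 for the ligands. SFRP1 lies in a segment of chromosome 8 that was high as a group. In the list of non-canonical Wnt and planar cell polarity genes, the receptor ROR2 was 25.2-fold higher, from 5 reads to 126 (10.52 to 78.95). Its relative ROR1 was 5.74-fold lower (3.80 to 8.99), and CELSR2 was 4.98-fold higher (4.11 to 6.06). The 14 measured members had a median of 0.18 (percentile 74.8).

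Breast cancer stem cell markers were divided. Of 10 measured members, 2 were at least 2-fold higher, 3 lower and 5 between, with a median of 0.19 (-0.98 to 1.17; percentile 86.6). ITGA6, an integrin subunit, was 3.22-fold higher (3.02 to 3.43) and THY1 2.09-fold higher (2.01 to 2.18). KLF4, a pluripotency factor, was 3.04-fold lower (2.75 to 3.36) and BMI1, a Polycomb protein, 2.14-fold lower (1.97 to 2.33). ALDH1A3 was the other lower member, and at equal totals 1 member was at least 2-fold lower.

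Mesenchymal and EMT genes were high as a group, with 11 of 22 measured members at least 2-fold higher and 1 lower. The median was 1.12 (-0.08 to 1.57) and above all 10000 random lists. SNAI1, an EMT transcription factor, was 8.83-fold higher, from 12 reads to 106 (4.85 to 17.6). COL3A1, a fibrillar collagen, was 5.22-fold higher (5.004 to 5.45) and SPARC, a matrix protein, 4.95-fold higher (4.76 to 5.14). CDH2, N-cadherin, was 6.09-fold lower (4.22 to 9.03). Of 6 measured epithelial genes, 3 were at least 2-fold higher and 1 lower, with a median of 0.70 (-1.30 to 3.22; percentile 93.9). KRT18 was 9.02-fold higher (7.45 to 11), CD24 3.14-fold higher (3.01 to 3.28), CDH3 2.51-fold higher and OCLN 2.84-fold lower (2.26 to 3.58). The 22 measured integrin and basement membrane genes had a median of 0.35 (percentile 99.02), and percentile 96.5 after the GC and length trend was removed. Of these, 3 were at least 2-fold higher, ITGA6, HSPG2 and ITGA2, and 1 lower, LAMA3, whose log2 ratio with the pseudocount was -0.99 at equal totals.

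Genes of S phase, of cholesterol and fatty acid synthesis and of glycolysis also stood above the central 95% of random lists. All 26 S phase genes were measured, 4 at least 2-fold higher, 7 at equal totals, and 0 lower, with a median of 0.53 (0.41 to 0.97; percentile 99.99). E2F1, a transcription factor of the G1/S transition, was 2.796-fold higher (2.52 to 3.11), the licensing factor CDT1 2.60-fold, CCNE2 2.36-fold and PCNA 2.17-fold. By contrast, none of the 28 G2/M genes differed by 2-fold (median -0.19, percentile 18.5). Cholesterol and fatty acid synthesis genes had a median of 0.46 (0.29 to 1.03), above all 10000 random lists, with 6 of 26 at least 2-fold higher and 0 lower. FASN, fatty acid synthase, was 3.18-fold higher (3.09 to 3.27). MVD and FADS2 were 3.74-fold and 2.58-fold higher. Among 21 glycolysis genes, 5 were at least 2-fold higher and 0 lower (median 0.51, 0.21 to 1.10; percentile 99.93). SLC16A3, a lactate exporter, was 4.41-fold higher (3.86 to 5.04), ALDOC 4.06-fold, PFKFB4 4.32-fold and GAPDH 2.07-fold. The 15 fatty acid oxidation genes lay within the central 95%, with a median of 0.32 (percentile 96.4), and ACADS and ECI2 were the 2 members at least 2-fold higher. This list stood above it at percentile 98.06 after the GC and length trend was removed, and at 99.41 with segment medians removed as well.

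Lists tied to known substrates of SIK kinases had medians below that of all genes. CREB targets and immediate early genes had a median of -0.33 (-0.62 to 0.54; percentile 2.18), with 2 of 19 members at least 2-fold higher and 2 lower. Its mean, without the subtraction of the median of all genes, was -0.12, at percentile 35.5 among the means of random lists. FOS was 8.91-fold higher, from 33 reads to 294 (6.20 to 13.2), and EGR1 3.23-fold higher (2.78 to 3.77). ATF3 and PDE4B were 2.81-fold and 2.45-fold lower. Class IIa HDACs and MEF2 factors had a median of -0.42 (percentile 5.19, and 2.04 after the GC and length trend was removed), and HDAC9 was the 1 of 6 members at least 2-fold lower. Among 19 CDK inhibitors and p53 targets, 3 were at least 2-fold higher and 4 lower (median 0.11, percentile 83.2). CDKN1A, the inhibitor p21, was 6.66-fold higher (6.10 to 7.28), whereas PMAIP1, SESN2 and CDKN2B were 3.82-fold, 2.96-fold and 2.802-fold lower. CDKN2B lies in the low segment of chromosome 9.

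The other signalling lists lay within random lists or close to their edge. TGF-beta targets had a median of 0.17 (percentile 85.6), with 4 of 18 at least 2-fold higher, among them BMP2 and NOG, and 3 lower, among them LTBP1 and CDKN2B. Among 22 YAP/TAZ targets (median -0.21, percentile 13.3), 2 were at least 2-fold higher, with FOXF2 13.1-fold higher (7.59 to 24.4), and IGFBP3, NT5E and AJUBA were at least 2-fold lower. Hypoxia genes had a median of -0.21 (percentile 12.8), with 3 of 19 higher and 3 lower. Notch targets had a median of 0.54 (percentile 97.6), and percentile 29.7 after the GC and length trend was removed, with 2 of 11 at least 2-fold higher and 2 lower. Within that list JAG1 was 3.19-fold higher and NOTCH2 4.40-fold lower.

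Markers of other cell types were few among the measured genes. None of the 14 leukocyte markers and none of the 11 endothelial and adipocyte markers reached 1 FPKM, with 31 and 57 reads in all for leukocyte markers and 13 and 9 for the others, scrambled first. Luminal breast markers had a median of -0.18 over 5 measured genes (percentile 35.9). Basal and myoepithelial markers had a median of -0.48 over 7 (percentile 6.75, and 1.26 after the GC and length trend was removed), with KRT14 6.57-fold lower, from 46 reads to 7 (2.95 to 17.3), and FOXC1 2.02-fold lower, short of 2-fold at equal totals. Genes often used as loading references had a median of -0.14 over 14 genes (percentile 36.4), yet SDHA and GAPDH were 2.36-fold and 2.07-fold higher and TBP 2.09-fold lower, the last short of 2-fold at equal totals.

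Library composition differed slightly. Genes of the mitochondrial chromosome took 7.35% of reads in the scrambled library (Wilson 95% interval 7.34 to 7.36) and 8.71% in the shSIK2 library (8.70 to 8.73). The 13 mitochondrially encoded protein genes had a median of 0.42 (percentile 99.6 among matched and 94.5 among unmatched random lists), and MT-ND6 alone was at least 2-fold higher, at 2.18-fold. Ribosomal proteins took 4.89% and 5.47% of reads, and the 30 listed had a median of 0.08 (percentile 83.6) with 0 at 2-fold; without the subtraction the median was -0.03 and the mean 0.006. The 10 highest genes took 8.71% and 9.79%. Without mitochondrial genes the 10 highest took 5.29% and 5.91%, and ribosomal proteins 5.28% and 5.99%. Replication-dependent histones, whose transcripts mostly lack a poly(A) tail, had a median of -1.04 (-2.28 to 1.78; percentile 0.03), with 5 of 8 measured members at least 2-fold lower and 1 higher. HIST1H1E had 16 reads against 2, 8-fold lower (1.88 to 71.7). HIST1H1C was 3.24-fold lower (2.66 to 3.95), HIST1H2AC 3.14-fold lower (2.86 to 3.45) and HIST1H3B 3.31-fold higher (1.75 to 6.70).

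**Figure D3:**
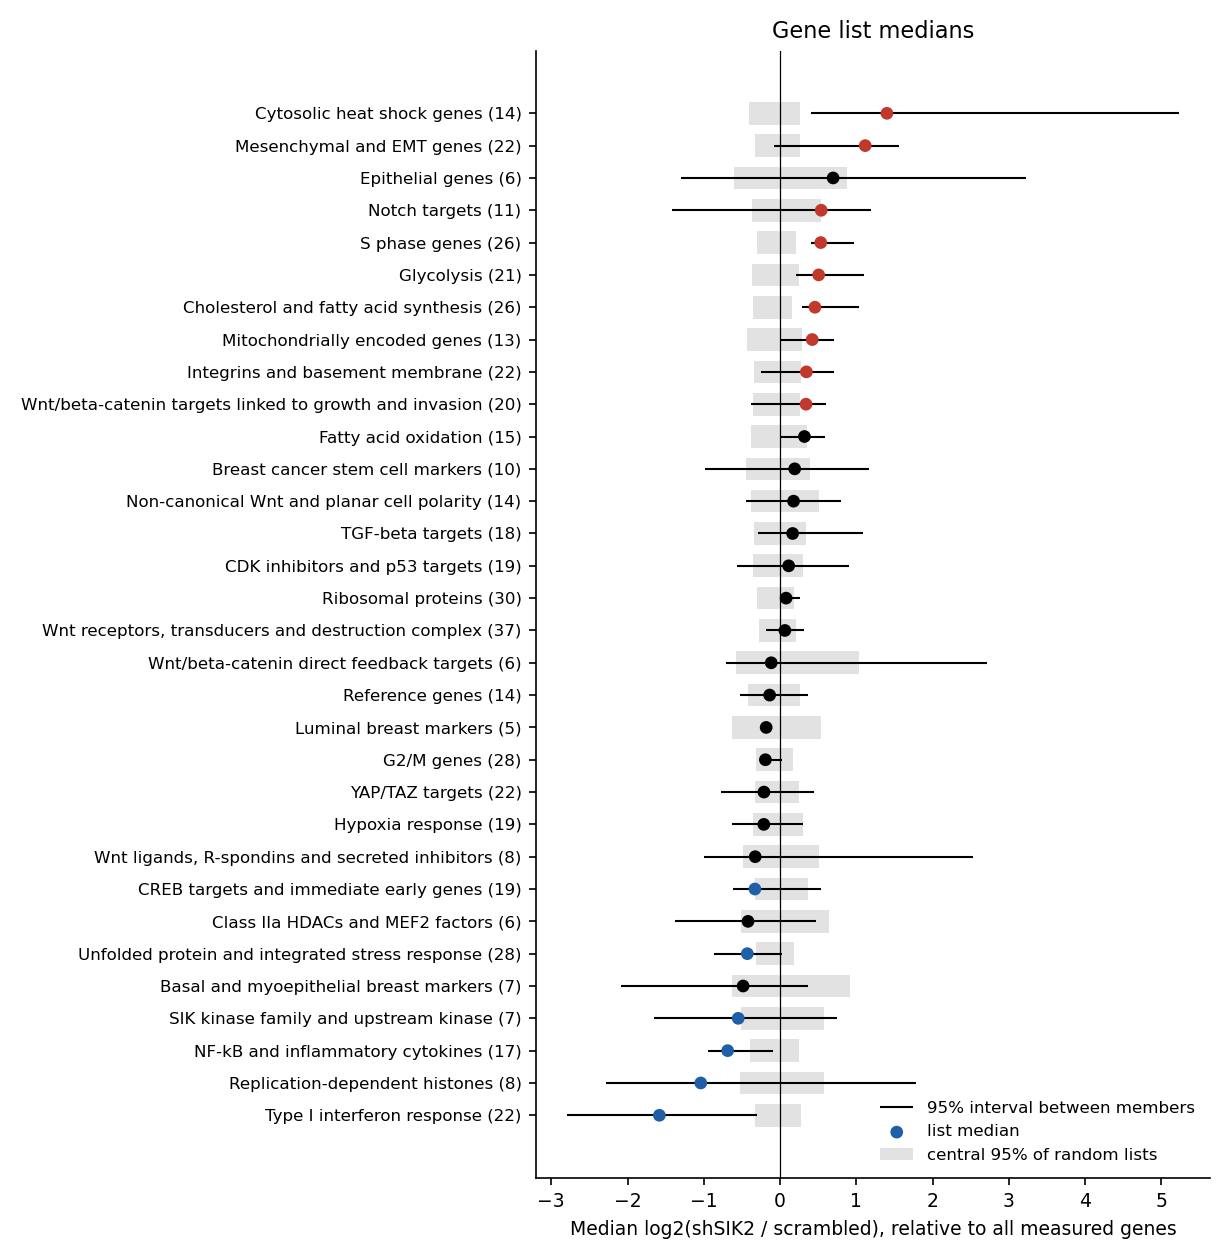
Median log2 ratio of shSIK2 over scrambled, relative to all measured genes (x axis), for each gene list with measured members (number in parentheses). Points are list medians (red above and blue below the central 95% of random lists), lines the 95% order-statistic interval where at least 6 members were measured, and grey bars the central 95% of 10000 matched random lists. Heat shock genes sit highest at 1.40 and interferon-response genes lowest at -1.58.

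Ratios also differed by chromosome region, an arrangement examined only after the data had been seen. After the GC and length trend was removed, the 10640 protein-coding genes of chromosomes 1 to 22 and X fell into 30 segments, with 7 splits. In 11 segments, holding 29.1% of the genes, the median lay over 0.2 from 0, in 6 below and in 5 above. On chromosome 12, 302 genes up to 63.7 Mb had a median of 0.10 (order-statistic interval 0.03 to 0.18), and the 259 genes from 63.8 Mb to the end had -0.38 (-0.44 to -0.28), with 75.7% of them below 0. The first 34.6 Mb of chromosome 9 had -0.49 over 81 genes (-0.60 to -0.28), and 119.6 to 248.9 Mb of chromosome 1 had -0.26 over 489 genes. Highest was the segment of chromosome 8 up to 42.6 Mb, with 0.38 over 126 genes (0.23 to 0.53), followed by chromosome 6 from 44.2 Mb (0.27) and the whole of chromosome 5 (0.26). Among all protein-coding genes at least 2-fold different in the shifted segments, 424 differed in the direction of their segment and 143 against it, and these genes also enter the segment medians. Elsewhere 622 were higher and 414 lower. Of the genes picked by the naming rule and at least 2-fold different, 30 went with their segment. Another 8 went against it: HSPA6, TMEM102, ACADS and S100A4, higher in low segments, and OCLN, TBP, NT5E and AJUBA, lower in high segments. Among lower genes those that went with it are IFNB1, PTPRD and CDKN2B on chromosome 9, SLC6A15 and OASL on chromosome 12, PAPPA2, PHGDH, NOTCH2, EGLN1 and ATF3 on chromosome 1, and IL6, IGFBP3 and HDAC9 on chromosome 7. Among higher genes they include SFRP1 on chromosome 8, ARSI, TCF7, SPARC, EGR1 and SDHA on chromosome 5, CD24 on chromosome 6, FOS on chromosome 14, and SNAI1, E2F1, PCNA, BMP2 and JAG1 on chromosome 20. The segment medians reach at most 1.41-fold, on chromosome 19.

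**Figure D4:**
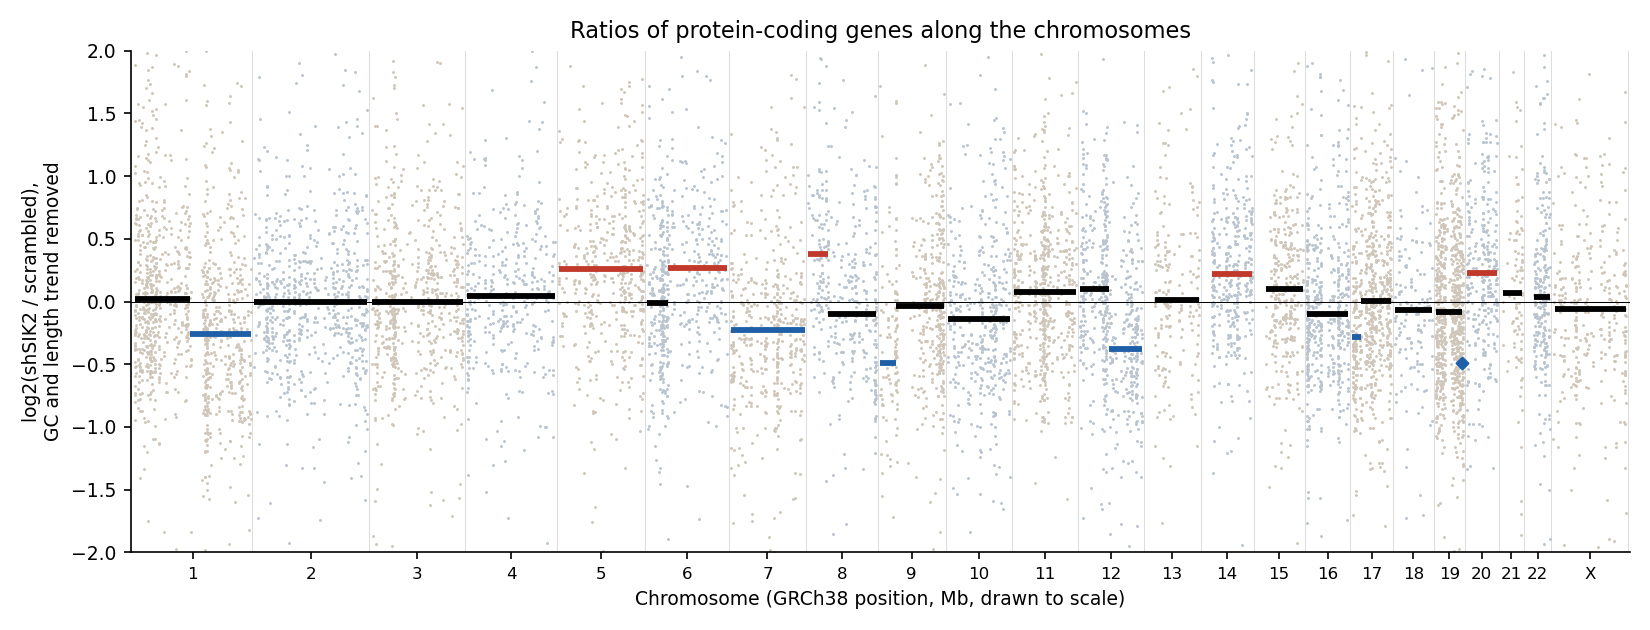
Log2 ratio of shSIK2 over scrambled after removal of the GC and length trend (y axis) for protein-coding genes (points) along GRCh38 chromosomes 1 to 22 and X (x axis, to scale), with bars at the median of each segment (red above 0.2, blue below -0.2, a diamond where a segment is under 10 Mb). The axis ends at 2 on both sides, which leaves 282 genes out of view. The bars step down within chromosomes 1, 8, 12 and 19 and up within chromosomes 6, 9 and 17.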

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

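TMM scaling of the recovered reads, the minimum of 50 reads and the removal of GC, length and segment trends were chosen as alternatives after the data had been seen. Over the 4 scalings the genes at least 2-fold higher ranged from 1414 to 1723 and those lower from 777 to 1065, within 1.5 times of the reported counts. Median of ratios scaling leaves the deposited values as they are, so it adds no check. The counts, higher first, were 760 and 621 with a pseudocount of 1, which shrinks ratios of low genes. They were 4008 and 2619 with a minimum of 0.1 FPKM and also with no minimum, where more genes enter, and 430 and 551 with a minimum of 5 FPKM, where fewer do and the lower genes outnumber the higher. A fold of 1.5 gave 2541 and 2735, and a fold of 4 gave 437 and 256. Protein-coding genes alone gave 897 and 708, and the Bonferroni-corrected counting interval left 935 higher genes. SIK2 stayed lower under each setting tried, with a log2 ratio of -0.97 at total count scaling and -0.95 with a pseudocount of 1, both short of 2-fold, and -1.03 with the GC and length trend removed.

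Of 340 list medians under alternatives, 338 stayed within the interval between members and kept any called sign. That is a weak criterion, since the interval can be wide (-1.30 to 3.22 for the 6 epithelial genes) and the scalings add at most 0.14. For this the median of all genes was added back after a trend was removed. Notch targets reversed, from a median of 0.43 to -0.20 with the GC and length trend removed and to -0.11 with segment medians removed as well. The cause was not tested beyond that removal. List percentiles moved in 17 of the cases tried and held in 76. Shares of reads moved in 10 of 10 cases without mitochondrial genes, beyond counting error. Ratios of named genes moved beyond their counting interval in 41 and held in 109, with no change of sign among those called. The authors' normalized values in place of counts were not run as an alternative, since the tables used here hold no counts, and with 1 library per group no replicate could be left out. Depth limits the genes with few reads most.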

Other observations

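Chosen only after the results were seen were the survey of gene families, the tests of the trend fitted at interferon members, of the lower interferon members, of shared heat shock reads and of distant neighbours, the splits along chromosomes and their distance to gene-free gaps. Families were taken from the letters that open a gene symbol, for 182 families with at least 8 measured protein-coding genes. Genes whose symbols open with HIST were low as a group. Of 19, 10 were at least 2-fold lower (8 at equal totals) and 1, HIST1H3B, higher. The median was -0.91 relative to all measured genes, below all 10000 random lists. It is the ratio of HIST1H2AI, which had 9 reads against 4. The lower members HIST1H1E, HIST2H2AC and HIST1H2BO also had few reads, at most 19 in the higher library. The family holds all 8 measured members of the replication-dependent histone list, so it is not separate support for that list. The ZNF family of zinc finger genes was lower by a small amount over 364 genes, with a median of -0.29, 49 members at least 2-fold lower and 11 higher, or 26 and 14 at equal totals. A segment of chromosome 19 from 55.4 to 58.6 Mb, a region known for such genes, had a median of -0.49 over 71 genes.

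The 6 families with the highest medians were HOXB, DHRS, MMP, ST, ADAMTS and COL. HOXB genes, a cluster of homeobox genes, had a median of 1.03 over 8 members, 4 of them at least 2-fold higher and 0 lower. HOXB6 went from 3.76 FPKM in the scrambled library to 10.8 in the shSIK2 library. DHRS genes, short-chain dehydrogenases, had a median of 0.96 over 8 members, 2 higher (4 at equal totals) and 0 lower. Symbols that open with ST had 0.83 over 16 members, 5 higher and 0 lower, and ADAMTS proteases 0.77 over 8, 3 higher and 0 lower. The 15 genes whose symbols open with COL, which besides collagens include COL4A3BP, a lipid transfer protein, had a median of 0.75, with 5 higher and 2 lower, or 6 and 1 at equal totals. COL12A1 stood at 14.6 and 41.2 FPKM, scrambled first, whereas COL15A1 went the other way, at 23.7 and 3.07. Genes whose symbols open with MMP, matrix metalloproteinases apart from MMP24OS, had a median of 0.94 over 10 members, 4 higher (5 at equal totals) and 0 lower. Solute carriers had a small shift of 0.20 over 171 members, 29 higher and 5 lower, or 35 and 4 at equal totals. Of the genes with at least 100 reads in the higher library, 30 differed by at least 16-fold once 0.5 reads had been added to each library, 13 lower in the scrambled and 17 lower in the shSIK2 library. Whether these 30 genes cluster by chromosome was the question first set; the runs of neighbouring genes described last were taken up in its place after both results had been seen. Chromosome 9 held the most of them, 16.7%, under the 23.1% that 95% of random draws stayed below. On it IFNB1, PTPRD, ADAMTSL1 and NTRK2 were lower in the shSIK2 library and ROR2 was higher. The 16.7% pools both directions and the whole chromosome, so it cannot show clustering within part of it. No whole chromosome's median lay further than 0.26 from that of all genes, under the limit of 0.5 set beforehand, though such medians do not show shifts of part of a chromosome. A different sub-population of cells in each culture was not testable with 1 library per group.

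Interferon-response genes were lower in the shSIK2 library together with IFNB1 itself. The GC and length trend as the whole cause is argued against, since the trend fitted at the 22 members lay between -0.23 and 0.71 relative to all genes, and the list median relative to all genes went from -1.58 to -1.73 on its removal. The interval between members after removal, -2.65 to -0.36, reached above the limit of -0.5 set beforehand, as it did before removal (-2.80 to -0.30), and all 13 members that were at least 2-fold lower stayed so. The state of a single culture, or a response to a vector unrelated to SIK2, cannot be told apart from an effect of the knockdown with 1 library per group. Hairpin and vector RNA can raise interferon genes, so a candidate explanation is a response in the scrambled culture, and an effect of SIK2 is the biological one left untested.

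Heat shock genes were higher in the shSIK2 library. The GC and length trend as the whole cause is argued against by a list median of 1.12 after its removal (0.53 to 4.94). Reads passing between HSPA1A and HSPA1B would leave their sum alone. Both genes were higher by themselves, so their summed reads had to be higher too, and went from 145 to 6672, 46.0-fold (39.0 to 54.6). Without HSPA1A, HSPA1B and HSPA6 the other 11 members had a median of 0.82 relative to all genes, but its interval of 0.27 to 1.52 reached below the limit of 0.5, so how far the list rests on those 3 genes stays open. Handling or heat in a single culture may give the same genes, and with 1 library per group it cannot be told apart from an effect of SIK2.

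Runs of neighbouring genes were shifted together along chromosomes. They were found in ratios from which the GC and length trend had been removed, with 7 splits. Genes 10 to 20 Mb apart had a correlation of 0.0297, above the highest of 100 shuffles (0.006). Co-regulation of close neighbours alone predicts no correlation on average at this distance. The shuffles also separated close neighbours, so their range is not the range that such co-regulation would give. They therefore cannot exclude it. The correlation came from the same ratios in which the long segments had been seen, so it largely restates them and is not separate support. A copy number difference between the cultures may be the source, and 3 of the 7 splits lay within 5 Mb of the widest gene-free gap of their chromosome, where 4.83% of those chromosomes' genes lie. It stays open, since the lower and upper expression classes were both shifted in 8 of 11 segments (72.7%), between the 80% and 50% limits. Those limits were set before this share was computed, though the runs were taken up after the data had been seen. Across all genes the classes were offset by themselves, at 0.11 (lower) and -0.10 (upper). The remaining segments fell short only in the class that this offset works against. These were the lower class on chromosome 1 from 119.6 Mb (-0.07) and chromosome 17 up to 19.0 Mb (-0.04), and the upper class on chromosome 14 (0.09). The share was not computed with the offset removed, so it cannot decide the question. If a copy number difference exists, part of the contrast between these libraries would belong to the cultures and not to SIK2. No segment median comes near the ratios of IFNB1 and PTPRD. Each segment holds at least 20 genes, so its median cannot show a change confined to single genes such as these.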
